A study of Mus musculus with 4 samples.

How the data were processed

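RNA-seq was measured in 4 libraries of CD-1 mouse embryos at E9.5: control brain, NTD brain, control spine and NTD spine, with 1 library per group. Grouping followed the sample titles, and all 4 value columns were mapped to a group. The authors deposited 1 table of FPKM, a read density scaled to gene length and library total, with 28765 genes and 4 columns. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.1 to mm10. The counting program, the annotation, the strand setting and any filter are not given in the sources used here.

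Gene identifiers were matched to GENCODE M21, an annotation of GRCm38 (mm10), for symbol, type, position and union exon length; 28698 identifiers matched and 67 did not. No gene was at 0 in all libraries. FPKM times union exon length stepped in whole multiples of 1 value per library, which gives the library total behind the deposited FPKM and the reads per gene. With a tolerance of 0.01 reads, 28298 genes (98.6%) came out whole in all 4 libraries, and the recovered reads summed to between 98.0% and 98.3% of the library totals. At the recovered totals 1 FPKM in a gene of 1000 bases stands for 16.9 reads in control brain, 16.5 in NTD brain, 16.3 in control spine and 16.6 in NTD spine. Among compared genes, 219 were not whole and have no interval.

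The main measure was the log2 ratio of (FPKM + 1) among the 12940 genes with a mean over the 4 libraries of at least 1 FPKM, of which 11199 are protein coding. Genes at or beyond 2-fold were counted in each direction. A fold named in the text is the ratio of recovered reads per library total, with an exact (Clopper-Pearson) conditional binomial interval at 95%. Against a library with 0 reads the fold is a lower bound computed against a floor of 3 reads in that library, and no fold is given when both are at or under the floor. The share of the counts that counting noise alone gives was found from 100 simulations in which both libraries drew reads from the pooled level; the simulations hold no variation between samples. Genes shared by both tissues were set beside the overlap of independent lists. GC content is that of the longest transcript of each gene in the same annotation.

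The steps were tested on simulated reads at the depth of NTD brain against control brain, for 12721 genes with 200 set to differ. Of the genes set to 3-fold, 84% passed 2-fold with a median log2 ratio of 1.36; of those set to 1.5-fold, 2% passed, with a median of 0.53. Among unchanged genes 54 passed, and intervals covered the set fold in 95.45% of genes.

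Before the data were examined, 39 gene lists were fixed: neural (progenitors, early neurons, forebrain and midbrain, hindbrain, trunk Hox, tail bud, ventral neural tube and Shh, roof plate and neural crest), closure (planar cell polarity, closure mutants), metabolism and stress (folate and one-carbon, nucleotide synthesis, p53 targets, integrated stress response, hypoxia and glycolysis, immediate early and heat shock, oxidative phosphorylation, mitochondrially encoded), cell cycle and chromatin (DNA replication, mitosis, DNA damage repair, DNA and histone methylation, ribosomal proteins, histones), signalling (Wnt targets, retinoic acid), other tissues (erythroid, endothelium, macrophages, somites, head mesenchyme, surface ectoderm, endoderm, heart, limb, placenta) and imprinted, housekeeping and sex chromosome genes. A list with at least 5 members past the filter, which 37 had, got its median and the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean expression. Percentiles describe these libraries and are not adjusted for the number of lists.

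The rule for naming genes was also fixed then. It names the 12 highest and 12 lowest per NTD comparison among genes with at least 5 FPKM in the higher library, the 8 most shared in each direction, the 5 with the largest difference between tissues in each direction, the 8 highest and lowest between the control tissues, and up to 4 members of each list described. Unnamed gene models and pseudogenes were counted but passed over when naming, and Tyms, haemoglobin, housekeeping, Xist and Y genes, Otx2 and trunk Hox genes could be named anywhere. Not every gene the rule gives is used here. Members that bring a list's count of genes past 2-fold to 5 or fewer were named as well.

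Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, rescaling each library to the same sum or by the median ratio, thresholds of 1.5-fold and 4-fold, and 5 expression bins. Those chosen after seeing the data were protein-coding genes only, log2 ratios adjusted for GC content and length in 10 by 10 cells of like genes, calls whose counting interval excludes equality, counts without genes that differ at least 2-fold between the control tissues, and random lists matched on GC content and length too. No p-value was computed, since genes are not replicates. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.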

Results

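Gene expression was measured by RNA-seq in brain and spine tissue of CD-1 mouse embryos collected at embryonic day 9.5 (E9.5), around the time the neural tube closes. The embryos with neural tube defects (NTD) came from parents kept over 8 weeks on feed low in folate, and the mothers received methotrexate (MTX), a folate antagonist, at 1.5 mg/kg on E7.5. The labels give the same protocol text for the controls and do not say whether control mothers received the diet or an injection. There were 4 libraries, 1 each of control brain, NTD brain, control spine and NTD spine, so no difference within a tissue, and no difference between the tissues in their ratios, has a replicate check. A difference shared by brain and spine rests on 2 pairs of libraries, 1 per tissue, and no p-value is given. Treatment is confounded with any batch of treatment, so the 2 pairs are not known to be independent. The library totals recovered from the deposited FPKM were 16911677 reads for control brain, 16470311 for NTD brain, 16272101 for control spine and 16605133 for NTD spine. Between 23389 and 24034 genes were above 0 per library, and 12940 genes with a mean of at least 1 FPKM were compared. Folds are ratios of recovered reads per library total with 95% counting intervals, which cover counting error only. List medians are log2 ratios of (FPKM + 1), and a list is said to stand apart when its median lies outside the central 95% of 10000 random lists matched on mean expression. Positions refer to GRCm38 (mm10).

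The libraries labelled brain and spine carried the regional genes of their tissue in the controls. In control brain the forebrain and midbrain patterning genes were higher, with 16 of 18 members at least 2-fold higher and a median of 1.81. Otx2, a homeobox gene of the anterior neural plate, was 12.3-fold higher (interval 10.4 to 14.6) and En2, a gene of the midbrain and hindbrain boundary, was 9.92-fold higher (8.10 to 12.3). All 22 trunk Hox genes, which set position along the trunk, were at least 2-fold lower in control brain, with a median of -3.43. Hoxb9 stood at 0.0919 FPKM in control brain and 47.5 FPKM in control spine, and Hoxb7 had 0 reads against 509, at least 176-fold lower. The spine library also held tissue of the trunk outside the neural tube: all 14 heart genes (median -3.26) and all 6 endoderm, liver and yolk sac genes (median -3.91) were at least 2-fold lower in control brain. Afp, which encodes alpha-fetoprotein, was at 56.7 FPKM in control spine with 0 reads in control brain.

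Other lists also differed between the control tissues, though not all by region. Hindbrain patterning genes, of a brain region, were lower in control brain in 9 of 12 members. Somite genes had a median of -1.68 in control brain against control spine, limb and lateral plate genes -1.61, tail bud genes -1.58, hindbrain patterning genes -0.97, imprinted genes -0.60, primitive erythroid genes -0.58 and retinoic acid pathway genes -0.34. Early neuron genes (0.52) and neural progenitor genes (0.53) were higher in control brain. Head mesenchyme genes were also higher (0.39), but their median was -0.20 when only genes with a mean of at least 5 FPKM were kept. In all, 127 genes were at least 2-fold higher and 308 at least 2-fold lower in control brain than in control spine, 80 and 234 of them protein coding; these counts were 26 and 113 with a pseudocount of 5 and 228 and 484 with a pseudocount of 0.1. Of the 37 lists with at least 5 members, 6 stood apart as higher and 16 as lower. Lists of randomly drawn genes would give 0.93 per side. Members of a list can vary together and some lists share members, so this is not the rate for these lists. The 8 highest genes by the naming rule were Aldh1a3, Cnpy1, En2, Lypd8, Nr2e1, Otx2, Tal2 and Trh, and the 8 lowest were Afp, Aldh1a2, Apoa1, Hoxb5os, Hoxb7, Hoxb8, Hoxb9 and Ttr. The strand setting of the authors' counting is not given in the sources used here, so reads of Hoxb5os and of the genes it runs against cannot be told apart.

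In brain, NTD against control, the highest protein-coding genes were immediate early genes, followed by Hoxb9 and heart genes. Fosb, which encodes a subunit of the AP-1 transcription factor (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051), stood at 0.0379 FPKM in control brain and 13.4 FPKM in NTD brain, a 354-fold difference (138 to 1300.1) that rests on 4 control reads. Fos, of the same gene family, was 37.7-fold higher (21.4 to 73.6) and Egr1, a zinc finger transcription factor, 11.1-fold higher (8.44 to 14.8). Myh6, which encodes the alpha myosin heavy chain of heart muscle (ENSMUSG00000040752, chromosome 14, 54941921 to 54966927), was 6.78-fold higher (5.80 to 7.98), at 1.59 FPKM in control brain and 10.8 FPKM in NTD brain.

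All 14 heart genes were higher in NTD brain, 10 of them at least 2-fold, and their median of 1.41 stood apart. Actc1, which encodes cardiac actin, was at 20.8 FPKM in control and 90.0 FPKM in NTD brain, a 4.34-fold difference (3.96 to 4.76), while Tbx5 and Nkx2-5, transcription factors of the early heart, were 2.35-fold (1.38 to 4.13) and 2.75-fold (1.72 to 4.55) higher. All 22 trunk Hox genes were also higher, with a median of 0.55, and 4 of them were at least 2-fold higher: Hoxb7, Hoxb8, Hoxb9 and Hoxc6. Hoxb9 (ENSMUSG00000020875, chromosome 11, 96271457 to 96276595) was 45.4-fold higher (17.4 to 168.6), at 4.18 FPKM in NTD brain, which remained far below its 47.5 FPKM in control spine. Hoxb8 had 67 reads in NTD brain and 0 in control brain, at least 22.9-fold higher. Somite genes stood apart as higher (median 0.20, 12 of 15 members higher), with Meox1, a homeobox gene of the somites, 3.25-fold higher (2.66 to 3.99) and Myog, a muscle transcription factor, 7.19-fold higher (2.15 to 37.6) on 3 control reads. Limb and lateral plate genes (0.14, 8 of 13 members higher) and tail bud genes (0.09) stood apart as higher too. The tail bud list was split evenly, with 6 members higher and 6 lower: T, the brachyury gene, was 3.59-fold higher (1.86 to 7.499) and Wnt3a, a signal of the tail bud and dorsal neural tube, 1.65-fold lower (1.37 to 1.99). Aldh1a2, a retinoic acid synthesis enzyme, was 8.32-fold higher (5.21 to 13.98), the only member of the retinoic acid list at least 2-fold different. Like the heart and trunk Hox genes, Aldh1a2 was far lower in control brain than in control spine. For these genes and the somite, limb and tail bud lists, a difference in tissue content between the brain libraries cannot be told apart from one in expression.

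Early neuron genes were lower in NTD brain in all 25 measured members, with a median of -0.56 that no random list reached. Nefm, which encodes a neurofilament subunit (ENSMUSG00000022054, chromosome 14, 68082590 to 68124846), was 2.005-fold lower (1.83 to 2.19). At the other end of the list, Ebf3 was 1.08-fold lower (0.985 to 1.19) and Isl1 1.03-fold lower (0.887 to 1.20). No member reached 2-fold on the scale of FPKM + 1. Neural progenitor genes were lower in 16 of 17 members, with a median of -0.24, and the Notch target Hes5 was 1.961-fold lower (1.48 to 2.62). Head mesenchyme genes (-0.19, with Col1a1 2.04-fold lower) and ventral neural tube and Shh signalling genes (-0.19, with Shh itself 1.48-fold lower, 1.30 to 1.68) were the other lists that stood apart as lower. The log2 ratios in brain had a trend with GC content (Spearman's rho across genes -0.34): the 10% of genes lowest in GC had a median of 0.0661 and the 10% highest in GC -0.154. Among protein-coding genes with a mean of at least 20 FPKM rho was -0.546, with medians of 0.129 and -0.163. Between control brain and control spine rho was smaller, at -0.129 across all genes and -0.29 in that set. Against random lists matched on GC content and length as well, the Shh and mitochondrially encoded lists no longer stood apart and the early neuron, neural progenitor, head mesenchyme, heart, Hox and somite lists still did. The limb and lateral plate and Shh lists also lay inside the range among genes with a mean of at least 5 FPKM, and the limb list and the tail bud list did so with a pseudocount of 5, the latter also without a filter.

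**Figure D1:**
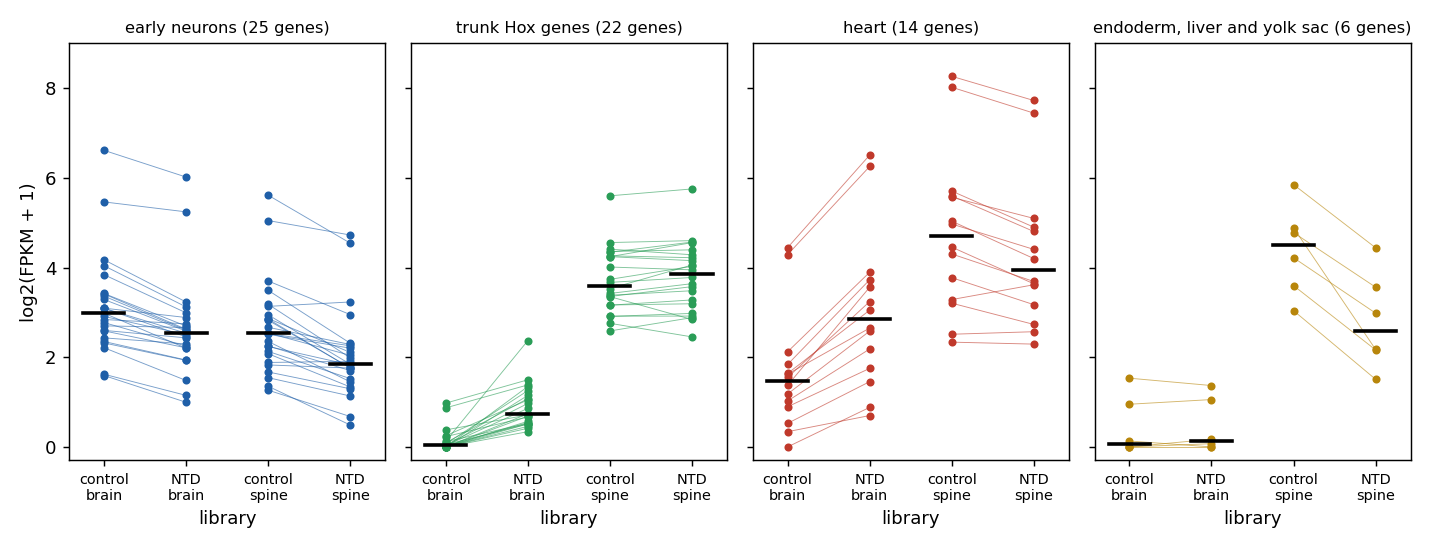
Level of each member of 4 gene lists, as log2 of (FPKM + 1) on the y axis, in the 4 libraries on the x axis; lines join the control and NTD library of a tissue and black bars are medians over the list. The 14 heart genes lie higher in NTD brain than in control brain, and all 6 endoderm genes lie lower in NTD spine than in control spine.

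Across all genes, 104 were at least 2-fold higher and 101 at least 2-fold lower in NTD brain, and 95.4% of genes lay within 1.5-fold. Counting noise alone, drawn from equal levels, gave at most 37 higher and 40 lower genes in 100 simulations, which leaves out the variation between samples. The counts move with the processing: 27 and 11 with a pseudocount of 5, 230 and 214 with a pseudocount of 0.1, and 51 higher without genes that differ at least 2-fold between the control tissues. Many of the called genes were short: 52 of the higher and 59 of the lower were models under 300 bases, such as microRNA and snoRNA genes, whose reads cannot be told apart from those of the host genes around them. Among protein-coding genes the counts were 35 higher and 9 lower. The 12 highest named genes were Fosb, Fos, Egr1, Myh6 and 8 short RNA genes with 7 to 95 reads in the higher library (Mir6976, Mir6993, Mir7-1, Mir1957a, Snord73a, Mir5098, Mir7030 and Snord110). The 12 lowest were 7 short RNA genes (Mir363, Snora17, Mir7651, Snord89, Snord88c, Mir3060 and Mir219a-2), the noncoding Snhg20 and Gt(ROSA)26Sor, the immunoglobulin kappa constant gene Igkc, and the protein-coding Lypd8 and Spaca6. Lypd8, an intestinal epithelial gene, had 145 reads in control brain and 0 in the other 3 libraries.

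In spine, NTD against control, the same 3 immediate early genes led the named protein-coding genes on the higher side and genes of the gut and yolk sac the lower side. Fosb was 24.3-fold higher (18.5 to 32.7), Egr1 7.95-fold (6.29 to 10.2) and Fos 7.41-fold (5.70 to 9.78). Apoa1, which encodes the main apolipoprotein of high-density lipoprotein (ENSMUSG00000032083, chromosome 9, 46228580 to 46230466), was 8.15-fold lower (6.37 to 10.6), at 28.6 FPKM in control spine and 3.51 FPKM in NTD spine. Afp was 2.74-fold lower (2.56 to 2.93) and Ttr, which encodes the thyroid hormone carrier transthyretin, 2.55-fold lower (2.09 to 3.14). All 6 endoderm, liver and yolk sac genes were at least 2-fold lower, with a median of -1.42.

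Primitive erythroid genes were lower in NTD spine in all 15 members, with a median of -0.75. The embryonic globins Hba-x (1682 FPKM in control, 843 in NTD spine) and Hbb-y (2233 and 1128) were 1.99-fold (1.95 to 2.04) and 1.98-fold (1.94 to 2.02) lower, and Hba-a1 alone passed 2-fold on the scale of FPKM + 1. Heart genes were lower in 12 of 14 members (median -0.57), among them Myl3 and Myh7, both 1.83-fold lower. Where the tissues were cut, and whether heart, gut and yolk sac were removed, is not given in the sources used here, so for the endoderm, erythroid and heart lists a difference in tissue content between the spine libraries cannot be told apart from one in expression. Forebrain and midbrain patterning genes, which were sparse in control spine, were lower in all 18 members (median -0.40). En2 was 17.5-fold lower (7.78 to 48.8) and Otx2 4.85-fold lower (3.29 to 7.34). For this list too, a difference in brain tissue between the spine libraries cannot be told apart from one in expression.

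Early neuron genes were lower in NTD spine in 23 of 25 members, 6 of them at least 2-fold, with a median of -0.59 that no random list reached. Nefm was 2.58-fold lower (2.29 to 2.91), while Ebf2 was 1.03-fold higher (0.873 to 1.20) and Isl1 1.08-fold higher (0.955 to 1.22). Neural progenitor genes had a median of -0.14, and Hes5, the 1 member past 2-fold, was 2.75-fold lower (1.92 to 4.003). On the higher side, hindbrain patterning genes (0.21), tail bud genes (0.15), somite genes (0.14) and trunk Hox genes (0.08) stood apart. Msgn1, a transcription factor of presomitic mesoderm, was 2.85-fold higher (1.90 to 4.37), and Cdx4, a regulator of posterior Hox genes, 1.97-fold higher (1.63 to 2.39). Nuclear-encoded oxidative phosphorylation genes (-0.13) and ribosomal protein genes (-0.09, with Rps2 2.14-fold lower and Rpl35a 2.48-fold higher) stood apart as lower, and DNA replication (0.10), DNA damage repair (0.09), DNA and histone methylation (0.08) and mitosis genes (0.06) as higher.

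The trend with GC content was of like size in spine (rho -0.36, with medians of 0.0585 in the 10% lowest in GC and -0.173 in the 10% highest), and longer genes had higher ratios (rho 0.20). Among protein-coding genes with a mean of at least 20 FPKM rho in spine was -0.504 with GC content and 0.353 with length. With random lists matched on GC content and length too, the neural progenitor, mitosis and ribosomal protein lists no longer stood apart in spine, and 15 of the 18 lists still did. The neural progenitor and mitosis lists also lay inside the range among genes with a mean of at least 5 FPKM, the former with a pseudocount of 0.1 and the latter among protein-coding genes only too, and the methylation list did so with a pseudocount of 5. With log2 ratios adjusted for GC content and length, the neural progenitor, mitosis, DNA damage repair and methylation lists lay inside the range in spine. In all, 84 genes were at least 2-fold higher and 88 at least 2-fold lower in NTD spine, of which 11 and 31 were protein coding and 61 and 40 were models under 300 bases. Counting noise alone gave at most 36 higher and 38 lower. The counts were 16 and 13 with a pseudocount of 5 and 134 and 246 with a pseudocount of 0.1. The 12 highest named genes were Fosb, Fos, Egr1, Msgn1, Rpl35a and 7 short RNA genes (Snord32a, Mir6976, Mir1957a, Mir1964, Snora30, Mir453 and Snord110). The 12 lowest were Apoa1, Apoa2, Apom, Afp, S100g, Hist3h2ba, the noncoding Rab26os and 5 short RNA genes (Mir322, Mir1258, Mir219a-2, Snora17 and Mir3060).

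The ratios of both tissues share no library and were correlated across genes (Pearson's r 0.40, Spearman's rho 0.46), though genes are not independent replicates. Any batch of treatment could be shared by both tissues and cannot be told apart from treatment here. The genes at least 2-fold higher in both tissues numbered 31, where independent lists would share 0.675, and 20 were at least 2-fold lower in both, where independent lists would share 0.687. Most were short models: the protein-coding genes higher in both were Fosb, Fos, Egr1 and Rpl35a, and those lower in both were Spaca6 and Atoh1, a proneural gene named after its values were seen. Rpl35a was 2.82-fold higher in NTD brain (2.65 to 2.998) and 2.48-fold in NTD spine (2.32 to 2.66), but it encodes a ribosomal protein with many processed pseudogenes, so its reads are uncertain. Spaca6, which encodes a sperm membrane protein and hosts microRNA genes, was 2.69-fold lower in brain (2.37 to 3.06) and 2.76-fold lower in spine (2.42 to 3.15), and the snoRNA host gene Snhg20 3.11-fold (2.57 to 3.78) and 2.86-fold lower (2.33 to 3.53). The naming rule for genes shared by both tissues gave Fosb, Fos, Egr1 and 5 short RNA genes on the higher side and Snhg20, Spaca6 and 6 short RNA genes on the lower side. In protein-coding genes with a mean of at least 20 FPKM the correlation was 0.48, and 0.42 after an adjustment for GC content and length.

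**Figure D2:**
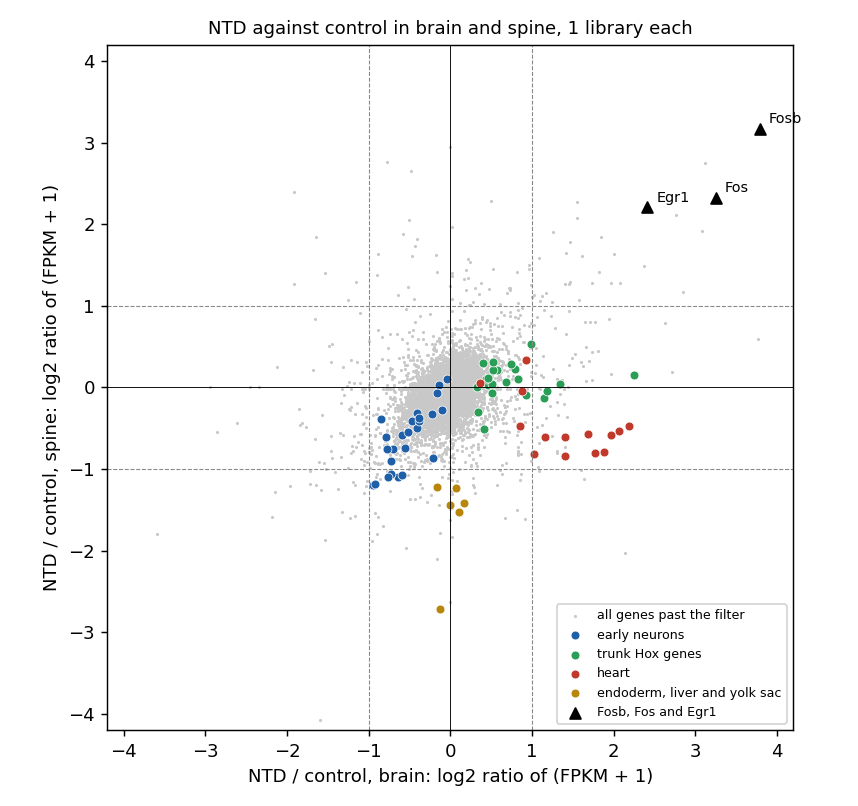
Log2 ratio of (FPKM + 1), NTD over control, in brain on the x axis and in spine on the y axis, 1 point per gene. Fosb, Fos and Egr1 lie at the upper right, at 3.79 and 3.17, 3.25 and 2.33, and 2.41 and 2.21, and heart genes lie to the right of 0 in brain and mostly below 0 in spine.

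The immediate early and heat shock list stood apart as higher in both tissues, with a median of 0.36 in brain (13 of 14 members higher) and 0.42 in spine (11 of 14 higher). Fosb, Fos and Egr1 passed 2-fold in both tissues and the small heat shock protein gene Hspb1 in brain, where its log2 ratio was 1.31 against -0.80 in spine. Like the heart genes, Hspb1 was far lower in control brain (2.58 FPKM) than in control spine (24.9 FPKM). At the low end, Ier3 was 1.44-fold lower in brain (0.800 to 2.63) and 1.29-fold lower in spine (0.804 to 2.09).

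MTX acts on folate metabolism, and no gene of that pathway passed 2-fold on the scale of FPKM + 1. Tyms, which encodes thymidylate synthase, was 1.08-fold higher in NTD brain (1.01 to 1.15) and 1.04-fold higher in NTD spine (0.973 to 1.11). The folate and one-carbon list had medians of 0.06 in brain and -0.0025 in spine, both inside the central 95% of lists matched on expression. The brain call is at the border: this list stood apart as higher with a pseudocount of 0.1 (0.071), with a mean of at least 5 FPKM (0.10), after rescaling to the same sum (0.027), among protein-coding genes only, and with either adjustment (0.12) or matching for GC content and length. Folr1, which encodes a folate receptor, was at 1.77 FPKM in control spine and 0.524 FPKM in NTD spine, 3.37-fold lower (2.02 to 5.86). In brain Folr1 was at 1.673 FPKM in control and 1.771 FPKM in NTD. The endoderm, liver and yolk sac list was also lower in NTD spine (median -1.42). For Folr1 in spine too, a difference in tissue content cannot be told apart from one in expression. Genes of nucleotide synthesis, which uses folate cofactors, stood apart as slightly higher in both tissues, with a median of 0.12 in each and 21 and 19 of 26 members higher. Atic, a purine synthesis enzyme, was 1.28-fold higher in NTD brain (1.23 to 1.34), and Cad, a pyrimidine synthesis enzyme, 1.28-fold higher in NTD spine (1.23 to 1.33).

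Several lists of neural tube closure and cell stress, given next with others, lay inside the central 95% in both tissues. The immediate early and heat shock list stood apart in both tissues. DNA damage repair stood apart as higher in spine and Shh signalling as lower in brain. Medians in brain and spine were -0.05 and -0.01 for planar cell polarity, -0.04 and 0.03 for genes whose mouse mutants fail to close the neural tube, -0.08 and -0.12 for p53 targets, 0.02 and -0.04 for the integrated stress response, and 0.06 and -0.03 for hypoxia and glycolysis. They were -0.04 and 0.07 for Wnt targets, -0.03 and -0.02 for the retinoic acid pathway, -0.13 and -0.13 for roof plate and neural crest, and 0.08 and -0.0046 for surface ectoderm. Endothelium gave -0.09 and 0.0032, imprinted genes 0.05 and 0.05, replication-dependent histones -0.03 and -0.13 (past 2-fold were Hist1h2bj, higher in brain, and Hist3h2ba, lower in spine), housekeeping genes 0.10 and 0.04, and sex chromosome genes 0.10 and -0.01. Some of these depended on GC content and length: with log2 ratios adjusted for both, the integrated stress response list stood apart as higher in brain (0.10) and spine (0.11), hypoxia and glycolysis (0.13) and surface ectoderm (0.14) as higher and roof plate and neural crest (-0.13) as lower in brain, and retinoic acid genes (0.13) as higher in spine. With random lists matched on both, hypoxia and glycolysis in brain, surface ectoderm in both tissues and Wnt targets in spine stood apart as higher. Within the closure list, Nog, which encodes a BMP antagonist, was 1.88-fold lower in NTD brain (1.40 to 2.54) and Grhl3, a surface ectoderm transcription factor, 1.56-fold higher (1.09 to 2.24). Lists inside the range in brain alone were hindbrain patterning (-0.08), forebrain and midbrain patterning (-0.14), endoderm (0.04), primitive erythroid cells (-0.01), oxidative phosphorylation (0.0029), DNA replication (0.04), mitosis (0.04), DNA damage repair (0.04) and DNA and histone methylation (-0.08). In spine alone they were Shh signalling (-0.07), head mesenchyme (-0.14), mitochondrially encoded genes (-0.02) and limb and lateral plate (0.02). Head mesenchyme in spine stood apart as lower with a pseudocount of 5 (-0.13), without a filter (-0.16) and with adjustment for GC content and length (-0.12), and with a mean of at least 5 FPKM endothelium in brain (-0.21) and roof plate and neural crest in spine (-0.16) did so. Surface ectoderm in brain stood apart as higher with a pseudocount of 5 (0.066), with a mean of at least 5 FPKM (0.17) and among protein-coding genes only, imprinted genes in spine with a pseudocount of 5 (0.048), histones in brain without a filter (0.046) and DNA replication in brain with adjustment for GC content and length (0.078). Of the macrophage and placenta lists 1 member each passed the filter: Cd68 was 1.17-fold higher in NTD brain (0.923 to 1.48) and Prl3b1 1.14-fold lower (0.635 to 2.05).

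**Figure D3:**
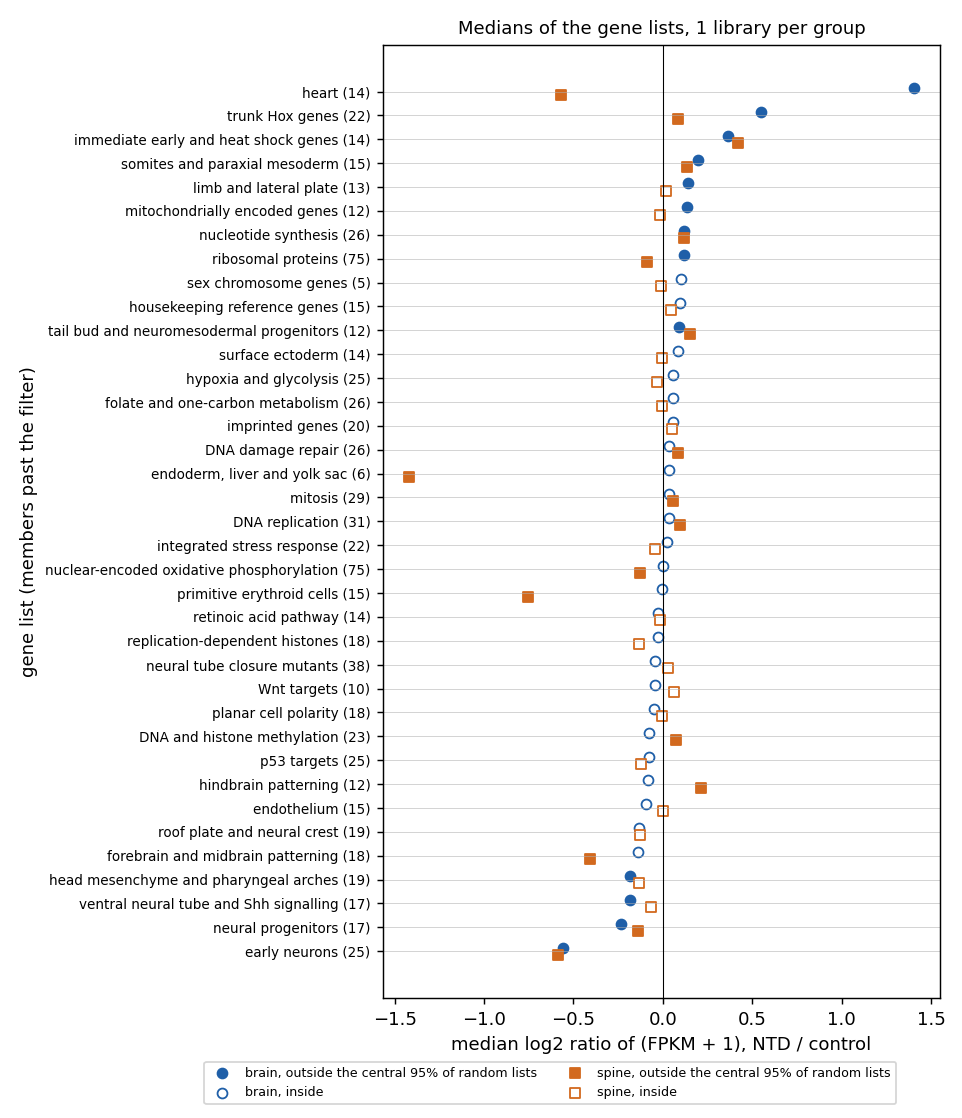
Median log2 ratio of (FPKM + 1), NTD over control, on the x axis for the 37 gene lists on the y axis, in brain (circles) and spine (squares); filled symbols lie outside the central 95% of random lists matched on mean expression. Early neurons lie lowest in brain at -0.56, and heart genes lie at 1.41 in brain and -0.57 in spine.

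Subtracting the spine ratio from the brain ratio set the tissues apart most in the heart (2.13), endoderm (1.51), primitive erythroid (0.70) and trunk Hox lists (0.52), all with higher values in brain. For 4 of the 6 endoderm genes, Afp, Apoa1, Apoa2 and Ttr, the value restates the lower level in spine, since they had at most 7 reads in either brain library. Ribosomal protein genes were also further up in brain, by 0.1979 in the median and in 75 of 75 members, with medians of 0.12 and -0.09. The mitochondrially encoded list, at 0.14 in brain, differed by a like amount (0.20), the oxidative phosphorylation list by 0.15, the histones by 0.16, surface ectoderm by 0.13 and forebrain and midbrain patterning by 0.20, which was 0.016 and inside the central 95% with a pseudocount of 5. Ratios rose with gene length in spine (rho 0.199) but not in brain (rho -0.0334). The mitochondrially encoded, oxidative phosphorylation and histone lists have median lengths of 870, 1718 and 622 bases. Their differences between tissues were not checked against gene length. Lists with lower values in brain were hindbrain patterning (-0.28), tail bud (-0.22), Shh signalling (-0.11), closure mutants (-0.10), DNA replication (-0.08) and neural progenitors (-0.08). The early neuron list differed by 0.05, inside the central 95%, but stood apart as higher in brain with a pseudocount of 0.1 (0.14) and among genes with a mean of at least 5 FPKM (0.18). Per gene, 149 differences were at least 1 and 92 were at most -1, against 35 and 18 with a pseudocount of 5 and 341 and 189 with a pseudocount of 0.1. The 5 highest named genes were Myh6, Myl2, Mir130b, Mir322 and Mir7030, and the 5 lowest were Lypd8, Pyy, Scarna17, Snord32a and Snord71. With 1 library per group the difference between tissues was not tested.

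Between the NTD tissues, 132 genes were at least 2-fold higher and 275 at least 2-fold lower in brain, 87 and 192 of them protein coding; the counts were 24 and 77 with a pseudocount of 5 and 272 and 454 with a pseudocount of 0.1. Forebrain and midbrain genes had a median of 2.14 and early neuron genes 0.67, while trunk Hox genes had -3.005, endoderm genes -2.18 and heart genes -1.16. The heart list had thus a smaller distance between the NTD tissues than between the control tissues. Primitive erythroid genes were higher in NTD brain than in NTD spine in 15 of 15 members (0.31), against 2 of 15 in the controls.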

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

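Among the results that stood out by rules fixed before the data were examined, 3 concerned opposite directions in brain and spine. Heart genes were higher in NTD brain (median 1.41) and lower in NTD spine (-0.57), with a median difference per gene of 2.13. Ribosomal protein genes were higher in NTD brain (0.1159) and lower in NTD spine (-0.08725), with a median difference per gene of 0.1979; the spine median lay inside the central 95% once random lists were matched on GC content and length. There were 10 genes at least 2-fold apart in opposite directions, of which 9 were models under 300 bases, 0 were protein coding and the remaining 1, Rps3a3, belongs to a family of ribosomal pseudogenes. None of these differences between brain and spine was tested, because each group has 1 library.

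All tests on the early neuron genes, which were lower in both NTD tissues, were chosen after the result was seen. Brain tissue in the control spine library explains little of the spine median of -0.59: taking control brain out of control spine at a share of 8.53% shifted the list by -0.0601. Gene length and GC content do not explain the medians either, since the medians lay at percentile 0 in brain and 0 in spine among lists matched on both. Trunk tissue like NTD spine in the NTD brain library explains little of the brain median of -0.56. Mixing NTD spine into control brain at the 5.41% share given by trunk Hox genes shifted the list by -0.0442. At the 34.6% share given by heart genes the shift was -0.309. The trunk Hox genes, and Afp with 7 reads against 62.1 needed at the Hox share, argue against whole NTD spine at the heart share. Tissue richer in heart than NTD spine was not modelled, so it stays open for part of the median. An earlier stage of the NTD embryos stays open too: Lin28a, Lin28b, Trim71 and Hmga2 had medians of 0.0454 in brain and 0.155 in spine, the ratio of Hbb-bh1 to Hbb-y was 1.18 and 1.12 times that of the controls, and the ratio of Hba-x to Hba-a1 was 1.09 and 1.04 times. What an earlier stage would give was written down after these values were known, the shifts are small and only their counting error is known, so replicate litters matched by somite number would be needed to tell an earlier stage from fewer neurons at the same stage.

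All tests on the trunk Hox and heart genes, which were higher in NTD brain, were chosen after the result was seen. Gut or yolk sac tissue at the Hox share of NTD spine is argued against mainly by Afp, with 7 reads in NTD brain against 62.1 needed. Apoa1, Apoa2 and Ttr had 0, 0 and 1 reads against 3.86, 1.66 and 7.3 needed, which is too few to add much. Afp, Apoa1, Apoa2 and Ttr reached at most 0.137 of the level needed. Trunk and heart tissue in the NTD brain library cannot be told apart from other expression in brain cells. Without Hox and heart genes, 20 genes at least 8-fold higher in control spine than in control brain had a median of 0.67 in brain, with 15 higher and 8 at least 2-fold higher, but choosing genes low in control brain pushes this ratio up. The 8 such genes at least 8-fold higher in NTD spine than in NTD brain, a choice that pulls it down, had a median of 0.434, but 6 of them had at most 3 reads in control brain and so had little room to be lower. The shares given by Hox (5.41%) and heart genes (34.6%) differ, and no biological explanation of these lists was tested.

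The test of trunk tissue on the immediate early genes, which were higher in both NTD libraries, was chosen after the result was seen. Trunk tissue in the NTD brain library is argued against as the whole cause in brain, because NTD spine at the larger of the Hox and heart shares gives at most 0.376 of the level of Fosb, Fos and Egr1 in NTD brain. Different handling of the NTD embryos before lysis could not be told apart from an effect of the defect or the drug: the 5 heat shock genes had medians of 0.24 in brain and 0.302 in spine, above 0 but under the 0.5 written down before this test was run, and Hspb1 was at 1.31 and -0.80. Handling, treatment and phenotype are tied to the same groups here, and embryos dissected in mixed order would be needed to separate them.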

How the results depend on the processing

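The alternatives with pseudocounts, filters, rescaling, thresholds and expression bins were chosen before the data were examined; protein-coding genes only, the adjustment and the matching for GC content and length, the counting interval and the removal of tissue genes were chosen after seeing the data. No paired analysis was possible within a tissue because each group has 1 library and the groups share only the replicate number 1; a model of condition with tissue as a block, which would leave 1 residual degree of freedom for a difference shared by both tissues, was not run. Of the list medians, 622 results under the choices fixed in advance and 255 under the later ones kept their side. Of log2 ratios of single genes, 4407 and 617 stayed within their counting interval or near it, and 367 and 227 did not. With a mean of at least 5 FPKM 76 of 95 list results had enough members to compute, and with protein-coding genes only 93 of 95; otherwise all 95 had. Where a list moved into or out of the central 95% the cause was not tested.

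Gene counts below run in the order NTD brain against control brain, NTD spine against control spine, control brain against control spine, and NTD brain against NTD spine, higher before lower; the main counts are 104 and 101, 84 and 88, 127 and 308, and 132 and 275. Genes differing between the tissues in their NTD ratio numbered 149 higher and 92 lower in brain.

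With a pseudocount of 0.1 the counts were 230 and 214, 134 and 246, 228 and 484, and 272 and 454, with 341 and 189 for the difference between tissues; a smaller pseudocount damps low values less by construction. The folate list in brain (0.071) and the early neuron list for the difference between tissues (0.14) came to stand apart, and the neural progenitor list in spine (-0.14) no longer did. With a pseudocount of 5 the counts were 27 and 11, 16 and 13, 26 and 113, and 24 and 77, with 35 and 18 for the difference. Surface ectoderm in brain (0.066), imprinted genes in spine (0.048) and head mesenchyme in spine (-0.13) came to stand apart, while tail bud (0.029) and limb genes (0.031) in brain, DNA and histone methylation in spine (0.042) and forebrain and midbrain genes in the difference (0.016) no longer did.

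Without a filter the counts were 164 and 171 in brain, 153 and 149 in spine and 203 higher between the control tissues, with 291 and 245 for the difference; more genes enter by construction. The correlation of the ratios of both tissues was 0.279 instead of 0.401. Histones in brain (0.046) and head mesenchyme in spine (-0.16) came to stand apart and tail bud genes in brain (0.0012) no longer did. With a mean of at least 5 FPKM, which leaves fewer genes, the counts were 52 and 25, 19 and 34, 31 and 108, and 38 and 97, with 66 and 11 for the difference and a correlation of 0.518. Head mesenchyme between the control tissues was reversed, at -0.20 instead of 0.39. In brain, folate (0.10), endothelium (-0.21) and surface ectoderm (0.17) came to stand apart, as did roof plate and neural crest in spine (-0.16) and early neurons in the difference (0.18). Shh signalling (-0.12) and limb genes (-0.033) in brain, and neural progenitors (-0.13) and mitosis (0.051) in spine, no longer stood apart.

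With a threshold of 1.5-fold the counts were 262 and 331, 188 and 379, 376 and 682, and 441 and 632; at 4-fold they were 17 and 9, 13 and 5, 28 and 125, and 30 and 75, both by construction. Rescaling each library to the same sum brought the folate list in brain (0.027) to stand apart and left the other 94 of 95 list results on their side. Rescaling by the median ratio and using 5 expression bins left all 95. The median log2 ratio of all genes was -0.0319 in brain and -0.0385 in spine; after rescaling to the same sum it was -0.0633 and 0.00816, and by the median ratio -0.0153 and -0.0202.

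With protein-coding genes only, which leaves out the short models, the counts were 35 and 9 in brain, 11 and 31 in spine, 80 higher between the control tissues and 87 higher between the NTD tissues, with 78 and 10 for the difference. Folate (0.057) and surface ectoderm (0.085) in brain came to stand apart and mitosis in spine (0.057) no longer did, because the random lists differ while the members do not. Asking that the counting interval excludes equality left 58 lower genes in brain and 52 higher and 58 lower in spine. Without the genes that differ at least 2-fold between the control tissues, 51 genes were higher in NTD brain and 63 in the difference between tissues.

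With log2 ratios adjusted for GC content and length, 80 of 95 list results kept their side. In brain, roof plate and neural crest (-0.13), folate (0.12), DNA replication (0.078), integrated stress response (0.10), hypoxia and glycolysis (0.13) and surface ectoderm (0.14) came to stand apart, and Shh signalling (0.018) and mitochondrially encoded genes (0.0501) no longer did. In spine, integrated stress response (0.11), retinoic acid (0.13) and head mesenchyme (-0.12) came to stand apart, and neural progenitors (-0.041), mitosis (0.039), DNA damage repair (0.062) and DNA and histone methylation (0.064) no longer did. With random lists matched on GC content and length too, medians stay the same by construction and 85 of 95 results kept their side. Folate (0.057), hypoxia and glycolysis (0.05971) and surface ectoderm (0.085) in brain, and Wnt targets (0.065) and surface ectoderm (-0.0046) in spine, came to stand apart. Shh signalling (-0.19) and mitochondrially encoded genes (0.14) in brain, and neural progenitors (-0.14), mitosis (0.057) and ribosomal proteins (-0.087) in spine, no longer did.

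Depth limits the low end: 1 FPKM in a gene of 1000 bases rests on 16.3 to 16.9 reads, so folds for genes under that level carry wide counting intervals, and microRNA and snoRNA models rest on few reads at much higher FPKM.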

Other observations

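Hspa5, Hsp90b1 and Manf, 3 genes of protein folding in the endoplasmic reticulum, were higher in both NTD tissues; the genes in this section were chosen after the values were seen, and no list of such genes was tested. The integrated stress response list, which holds Hspa5, lay inside the central 95% in both tissues (medians 0.02 and -0.04). It stood apart as higher in both (0.10 and 0.11) with log2 ratios adjusted for GC content and length. Among random lists matched on GC content and length it lay inside the range, at percentiles 95.86 in brain and 78.03 in spine. Hspa5, which encodes the chaperone BiP, was at 211 FPKM in control brain and 315 FPKM in NTD brain and at 201 and 307 FPKM in spine. Hsp90b1, an HSP90 family chaperone of the same compartment, was 1.34-fold higher in brain (1.30 to 1.39) and 1.52-fold higher in spine (1.47 to 1.56), and Manf, a secreted stress response factor, 1.27-fold (1.18 to 1.36) and 1.31-fold (1.22 to 1.42). Ccn1, which encodes a matrix protein induced by serum and stretch, was 2.05-fold (1.84 to 2.28) and 2.48-fold higher (2.24 to 2.74). Among single genes lower in both tissues, Mir17hg, host of the miR-17-92 cluster, was 2.12-fold lower in brain (1.94 to 2.31) and 1.95-fold in spine (1.79 to 2.14), and Snhg6, a snoRNA host, 1.91-fold (1.65 to 2.23) and 1.98-fold (1.70 to 2.30). Host genes as a class were not tallied. Leng8 was 1.62-fold (1.54 to 1.70) and 1.64-fold lower (1.56 to 1.73), and Rsrp1, an arginine and serine rich protein gene, 1.58-fold (1.501 to 1.66) and 1.77-fold (1.68 to 1.86). Ckb, which encodes brain creatine kinase, was 1.89-fold (1.79 to 2.01) and 2.11-fold lower (1.99 to 2.25).

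Control brain held reads of genes of adult intestine and plasma cells that had at most 4 reads in any other library. Lypd8 had 145 reads, Igha 91, Pigr 89, Zg16 61, Igkc 56, Muc3 53 and Clca1 45 in control brain. In NTD brain these genes had 0 reads apart from 2 of Clca1, in NTD spine 0 apart from 3 of Zg16 and 2 of Clca1, and in control spine 4 of Igkc and Clca1, 1 of Pigr, Zg16 and Muc3 and 0 of Lypd8 and Igha. With at least 20 reads in 1 library and at most 3 in the other 3 together, 4 protein-coding or immunoglobulin genes stood out for control brain (Lypd8, Igha, Pigr and Muc3), 1 for control spine (Slc7a9) and 0 for either NTD library.

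Xist was at 18.3, 15.2, 14.2 and 14.1 FPKM and the Y-linked Ddx3y at 3.42, 4.25, 5.61 and 5.61 FPKM in control brain, NTD brain, control spine and NTD spine, so transcripts of both sexes were present in every library. The labels do not give the number of embryos per library. The most abundant gene was the unnamed short model Gm23935, at 20642, 25892, 15695 and 13924 FPKM in the same order, in total RNA libraries whose FPKM summed to 332881, 341670, 329300 and 316771.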
